A study of Mus musculus with 36 samples.

How the data were processed

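RNA was measured in 36 mouse skin libraries: 16 wounds of the P arm, 17 wounds of the PD arm and 3 samples of unwounded skin. Wounds were snap frozen at 2, 4 or 12 days after injury and total RNA was extracted with TRIzol, per the labels' protocols. The same protocols give TruSeq Stranded mRNA preparation and a NovaSeq 6000 sequencer. The authors deposited read counts per gene for each library, as whole numbers without normalization. Reads were trimmed with Trimmomatic, aligned to GRCm39 with HISAT2 2.1.0, handled with SAMtools 1.9 and counted with HTSeq, per the submitters' processing notes. The notes state neither the strand setting of the counting nor the annotation release, so values of genes that overlap another gene on the opposite strand are less certain. Reads shared between close relatives, such as the Sprr2, Krtap, Krt6 and globin genes, are likewise uncertain.

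Each file held 55414 genes by Ensembl identifier, of which 1416 carried no symbol, and 0 entries named no gene. Totals ran from 11.807 to 58.376 M counts per library, with a median of 30.397 M. No 2 libraries of a group looked like the same library counted again, since the smallest chi-square per degree of freedom between replicates was 13.41. All libraries held Xist (128.66 CPM or more) and at most 10 counts over the Y genes, so every sample was female by expression and the planned sex term was not run. Coordinates came from a GENCODE annotation of GRCm39, in which 54749 of the 55414 identifiers (98.8%) were found. The annotation release the authors counted with may differ.

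Libraries were grouped by arm and day as labelled, in 7 groups. Counts were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3, with a mean per group over all 36 libraries. filterByExpr with a minimum count of 10 and a minimum total of 15 kept 20657 genes. Of these, 99.5% had a transcript model in the annotation. The comparisons were PD against P wounds at each day, the mean of these over days, the changes in that difference between days, P wounds of each day against unwounded skin, and P wounds between successive days. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 3 comparisons with unwounded skin share their controls, so no overlap or correlation between them is given. Where a gene had 0 counts in the lower group, its change is given as a bound that sets that group at 3 counts in all. Such bounds cover counting error only.

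Before the data were examined, 31 gene lists of skin, immune and other cell types, of the extracellular matrix and of p21, senescence and wound processes were fixed from general knowledge. Each was tested with fry (limma 3.58.1) on log2 CPM with a prior count of 2, adjusted over the lists of a comparison. A list needed at least 3 tested members. Because fry tests whether the list changed and not whether it changed more than other genes, camera was run beside it with an estimated correlation and with a preset correlation of 0.01. Members called are counted among all tested genes, and again with the adjustment over the list alone, a count given where it differs. Lists not mentioned for a comparison are part of its count of lists. Several lists share cell sources: skin holds most of their genes at some level.

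The genes named follow a rule fixed with the lists. It takes Cdkn1a in every comparison, then up to 10 higher and 10 lower genes past the threshold at a mean of at least 1 CPM, and up to 4 members of each list. For comparisons between days, the higher and lower genes were ordered by size of change among those whose levels do not overlap, and otherwise by adjusted p. The rule gives more genes than the text can hold, and the subset of 199 gene results followed up with every alternative was picked after the values were seen. Some genes that the rule gives are not reported here.

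Alternatives were DESeq2 size factors in the edgeR fit, no composition factor, the DESeq2 1.42.0 Wald test, limma-voom with sample weights, no filter, a stricter filter, robust fitting switched off, only the libraries of the comparison, each library left out in turn, the replicate number as a block, and omission of genes of muscle, fat, hair and blood. Added after the data were seen were 2 surrogate variables (sva 3.50.0), a term for 2 sets of wound libraries found in the data, fits within either set, and that term with limma-voom and with DESeq2. The sets were found by fitting group means plus a term with 2 values per library to log2 CPM, by turns from 6 starts, and keeping the smallest residual. Of the starts 4 came from the data alone and 2 from the replicate numbers. The sets kept were reached by 1 of the 4 and by the start that parted replicates 1 and 2 from the rest, and the other starts ended at larger residuals with 1 to 16 libraries placed otherwise. Groupings other than the labelled one were tested by refitting edgeR on the same libraries with labels exchanged. The code was tested on simulated data drawn from the real means and library sizes. In a further simulation 200 of the 20657 genes were changed by 1.5-fold, 2-fold or 4-fold, with genes drawn independently. The changed genes had a mean of at least 1 CPM and lay outside the lists, and the proliferation list was raised as well. No library sets were simulated, so the shares recovered hold for such genes in libraries without sets. They are given with the comparisons of the arms at each day and in the mean of days. The changes between days were not simulated.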

Results

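Polyadenylated RNA from mouse skin was measured by stranded sequencing in 36 libraries, 33 from wounds and 3 from unwounded skin. The wounds came from 2 arms, which the labels call P and PD without spelling the letters out, and were taken 2, 4 and 12 days after injury. The P arm had 5 libraries at day 2, 5 at day 4 and 6 at day 12, 16 wounds in all. The PD arm had 5, 6 and 6, 17 wounds in all. The unwounded skin carried no arm label. Each library held between 11.807 and 58.376 M counts in genes, with a median of 30.397 M. By group the totals ran from 23.419 to 47.378 M (P day 2), 30.154 to 44.56 (PD day 2), 19.888 to 39.792 (P day 4), 11.807 to 41.315 (PD day 4), 20.554 to 31.284 (P day 12), 16.146 to 35.659 (PD day 12) and 19.841 to 58.376 (unwounded). The series title concerns removal of skin cells with high p21, the product of Cdkn1a. Its questions were therefore what wounding changed over time within the P arm, and whether PD wounds differed from P wounds on each day. Levels are counts per M (CPM) after scaling, with the SD between libraries. Unless said otherwise, p-values of genes are from edgeR with Benjamini-Hochberg adjustment over 20657 genes and those of gene lists from fry with the same adjustment over 31 lists. They measure only the spread between these samples, since the labels say nothing of which animals the libraries came from.

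Cdkn1a (ENSMUSG00000023067, GRCm39 chromosome 17, 29309936 to 29319701, plus strand) was read in every library. It lay at 228 ± 29.7 CPM in unwounded skin (SD, n = 3; 193.6 to 246.1). In P wounds it lay at 372 ± 59 CPM at day 2 (n = 5; 300.1 to 462.8), 495 ± 134 at day 4 (n = 5; 381.9 to 717) and 266 ± 39 at day 12 (n = 6; 197.4 to 309.4). PD wounds held 316 ± 81.7 CPM at day 2 (n = 5; 225 to 415.7), 656 ± 188 at day 4 (n = 6; 389.9 to 823.4) and 351 ± 53.2 at day 12 (n = 6; 297.6 to 433.1). Within the P arm Cdkn1a rose 1.63-fold over unwounded skin at day 2 (log2 0.71, SE 0.23, edgeR, adjusted p = 0.0152) and 2.17-fold at day 4 (log2 1.12, SE 0.24, adjusted p = 0.00035). It fell 1.86-fold between days 4 and 12 (log2 -0.90, SE 0.19, edgeR, adjusted p = 0.000762). At day 12 it was not called against unwounded skin (log2 0.22, SE 0.22, adjusted p = 0.43), and with no composition factor it was called at 0.49. The call at day 2 was lost without unwounded replicate 2 (edgeR, adjusted p = 0.0599). Between the arms Cdkn1a passed the threshold on no day. The PD minus P log2 difference was -0.23 at day 2 (SE 0.20, edgeR, adjusted p = 1), 0.41 at day 4 (SE 0.19, adjusted p = 0.414) and 0.40 at day 12 (SE 0.18, adjusted p = 0.884). Before adjustment over genes the edgeR p of Cdkn1a, a gene fixed beforehand, was 0.244, 0.0393 and 0.0325 on these days. With a term for the library sets described further on the day 4 difference was 0.18 log2, and within the sets alone it was -0.06 and 0.11 at day 4 (set 2 with 1 P library) and -0.52 and 0.13 at day 2. With that term it was -0.17 at day 2 and 0.39 at day 12. With 2 surrogate variables the difference was -0.33 at day 2, 0.13 at day 4 and 0.22 at day 12. A whole biopsy holds Cdkn1a transcript from many cell types, so its level cannot check the arm labels the way a deleted gene would.

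**Figure D1:**
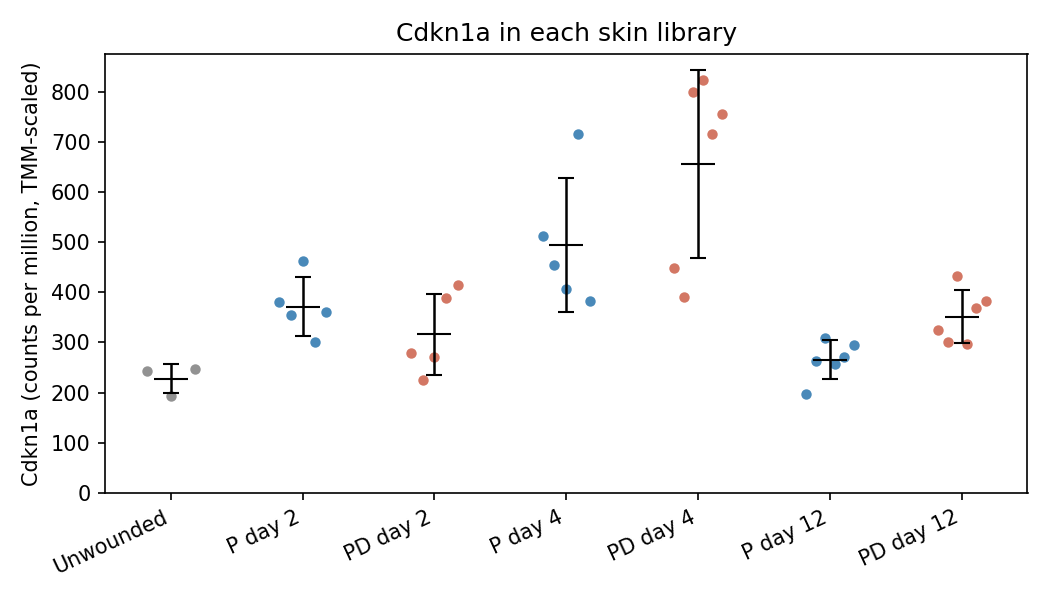
Cdkn1a in each of the 36 skin libraries. Each point is a library, in counts per M on a linear axis that starts at 0, by group on the horizontal axis, and the lines mark the group mean and SD. The PD day 4 libraries reach 823.4 CPM and the unwounded libraries lie between 193.6 and 246.1 CPM.

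At day 2 the P wounds held high levels of genes of neutrophils and inflammatory macrophages, while genes of the resting epidermis were lower than in unwounded skin. S100a9 (ENSMUSG00000056071, chromosome 3, 90599931 to 90603071, minus strand), which encodes a calcium-binding protein of neutrophils, rose from 0.173 ± 0.0821 CPM (n = 3) to 3370 ± 866 CPM (n = 5). Its partner S100a8 rose 4010-fold, and the iron-binding antibacterial gene Lcn2 rose 423-fold. Retnlg and Trem1 had 0 counts in unwounded skin, so their rise was at least 28200-fold and at least 10000-fold. All 14 neutrophil genes rose (fry, adjusted p = 3.07e-13; adjusted p = 0.0639 with an estimated correlation). All 14 monocyte and macrophage genes rose as well (fry, adjusted p = 1.21e-07; adjusted p = 0.314 with an estimated correlation), with Cd68 up 20.8-fold, Itgam 38.8-fold and the lipopolysaccharide co-receptor Cd14 436-fold. Of the alternatively activated macrophage genes, Arg1 rose 7.93-fold whereas Retnla fell 14.6-fold.

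Secreted factors rose with the myeloid genes in the P wounds at day 2. Of 24 genes on the senescence-associated secretory list, 21 rose and 0 fell, and 23 rose adjusted over the list alone (fry, adjusted p = 4.03e-10; adjusted p = 0.142 with an estimated correlation). Among them Timp1 rose 231-fold, Tnf 205-fold and Il6 at least 363-fold from 0 counts. Outside that list, the urokinase receptor gene Plaur (ENSMUSG00000046223, chromosome 7, 24161875 to 24175394, plus strand), a senescence marker, rose 222-fold and the growth factor gene Inhba 23.1-fold. Of 14 matrix protease genes 12 rose (fry, adjusted p = 5.62e-07; adjusted p = 0.314 with an estimated correlation), with Mmp12 up 38.2-fold and the neutrophil collagenase gene Mmp8 up 1230-fold. The matrix genes Tnc and Lox rose 49.8-fold and 13.7-fold. Hdc, which makes histamine, rose 367-fold. Junb rose 10.5-fold and Egr1 3.17-fold, and with them 9 of 10 immediate early genes (fry, adjusted p = 1.16e-05; adjusted p = 0.375 with an estimated correlation).

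Keratinocyte genes moved apart at day 2. Of 14 wound keratinocyte genes 11 rose, 12 adjusted over the list alone (fry, adjusted p = 6.52e-06; adjusted p = 0.375 with an estimated correlation), and Slpi and Sprr1b rose 1750-fold and 1220-fold. Of 14 differentiated keratinocyte genes 9 fell and 0 rose (fry, adjusted p = 0.00242; adjusted p = 0.63 with an estimated correlation). The suprabasal keratin genes Krt77 and Krt10 fell 22.4-fold and 12.1-fold. Of 9 basal keratinocyte genes 6 fell and 1 rose (fry, adjusted p = 0.000143; adjusted p = 0.475 with an estimated correlation), with Krt15 down 8.28-fold from 4550 ± 896 CPM (n = 3). Skint7 and Trdc, genes of the resident epidermal T-cell system, fell 47.6-fold and 3.37-fold. All 18 proliferation genes rose (fry, adjusted p = 2.29e-08; adjusted p = 0.314 with an estimated correlation). Birc5 (ENSMUSG00000017716, chromosome 11, 117740040 to 117746581, plus strand) rose 6.62-fold to 43.5 ± 5.64 CPM (n = 5) and Cdk1 rose 6.2-fold.

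Genes of other tissue in the biopsy also moved at day 2. The muscle differentiation gene Myog rose 14.6-fold and embryonic myosin Myh3 rose 12.6-fold, and 5 of 8 muscle regeneration genes rose (fry, adjusted p = 0.00129; adjusted p = 0.637 with an estimated correlation). The fat hormone gene Lep fell 10.1-fold, the smooth muscle gene Myl9 fell 4.02-fold and 7 of 9 Schwann cell genes fell (fry, adjusted p = 0.00472; adjusted p = 0.637 with an estimated correlation). The targets of p53 and p21 were mixed: 7 of 20 rose and 6 fell, with Bax up 2.35-fold and Trp53inp1 down 3.85-fold (fry for the list, up, adjusted p = 0.0113; adjusted p = 0.661 with an estimated correlation). Of 10 senescence marker genes 5 rose and 2 fell (fry, up, adjusted p = 4.94e-05; adjusted p = 0.637 with an estimated correlation). In all, 4609 genes were higher and 3926 lower in P day 2 wounds than in unwounded skin, 41.3% of those tested, and 3111 and 2119 of them differed by more than 2-fold. Of 31 lists 22 were called, 16 up and 6 down, and 0 with an estimated correlation. The largest adjusted p among the genes named for this day was 0.0152, that of Cdkn1a. Within set 1 of the wound libraries alone, a set described further on, Myh3 and the muscle regeneration list were no longer called, and limma-voom called 6223 genes lower.

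At day 4 the P wounds held inflammatory, muscle regeneration and matrix genes above the level of unwounded skin. S100a9 lay at 2210 ± 1580 CPM (n = 5), and all 14 neutrophil genes were up (fry, adjusted p = 2.14e-11; adjusted p = 0.152 with an estimated correlation). Retnlg was at least 7070-fold up from 0 counts, Cd14 352-fold, Chil3 477-fold and Lcn2 137-fold. The myosin gene Myh3 (ENSMUSG00000020908, chromosome 11, 66969126 to 66993117, plus strand) rose 727-fold to 340 ± 207 CPM (n = 5), and Mymk, which makes a protein that fuses muscle cells, rose 298-fold. Of 8 muscle regeneration genes 6 rose (fry, adjusted p = 8.84e-06; adjusted p = 0.412 with an estimated correlation). Of 16 genes of adult skeletal muscle 14 fell, all 16 adjusted over the list alone (fry, adjusted p = 0.00685; adjusted p = 0.51 with an estimated correlation), with Pvalb down 9.81-fold. All 14 adipocyte genes fell (fry, adjusted p = 0.000651; adjusted p = 0.412 with an estimated correlation), including Thrsp by 18.2-fold.

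The collagen gene Col1a1 (ENSMUSG00000001506, chromosome 11, 94827050 to 94843868, plus strand) rose 13.6-fold at day 4, to 4680 ± 2640 CPM (n = 5), Bgn rose 6.99-fold and Tnc 42.8-fold. Of 18 matrix collagen genes 13 rose, 17 adjusted over the list alone (fry, adjusted p = 0.000779; adjusted p = 0.482 with an estimated correlation). The collagenase gene Mmp13 rose 922-fold and Tgfb1 5.18-fold. All 14 wound keratinocyte genes rose (fry, adjusted p = 1.08e-08; adjusted p = 0.247 with an estimated correlation), with Slpi up 1670-fold and Sprr2d at least 3560-fold, though reads shared within the Sprr2 family leave the member uncertain. Krt14 rose 5.35-fold to 11800 ± 3000 CPM (n = 5) and Casp14 5.57-fold, whereas Krt15 fell 8.25-fold. On the senescence-associated secretory list 21 of 24 genes rose, 22 adjusted over the list alone (fry, adjusted p = 6.28e-09; adjusted p = 0.233 with an estimated correlation), with Il6 up at least 117-fold. The senescence marker Plaur rose 170-fold and the p53 target Pmaip1 4.31-fold.

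All 18 proliferation genes rose at day 4 (fry, adjusted p = 1.08e-08; adjusted p = 0.257 with an estimated correlation), with Birc5 up 7.54-fold and Cdk1 6.46-fold. The glycolytic gene Eno1 rose 3.62-fold, and 12 of 16 mitochondrial respiration genes fell (fry, adjusted p = 0.00171; adjusted p = 0.482 with an estimated correlation), with Sdha down 2.22-fold. All 9 Schwann cell genes fell (fry, adjusted p = 0.000651; adjusted p = 0.412 with an estimated correlation), the myelin gene Mbp by 3.01-fold. Fgf18 fell 35.1-fold. Of 18 hair follicle genes 15 rose, yet the list missed the threshold (fry, adjusted p = 0.104), and P day 4 replicate 3 alone held these genes at the level of day 12 wounds. Krt73 was at least 2790-fold up from 0 counts, and the call of Krt35 (330-fold) was lost without that replicate. Neither gene was called in a fit of only these 8 libraries. The fit called 4879 genes higher and 4066 lower, 43.3% of those tested, of which 3418 and 2062 by more than 2-fold, and 20 of 31 lists, 14 up and 6 down. Without P day 4 replicate 5 the hair follicle list was called, and without unwounded replicate 2 the lower genes numbered 2710. Within set 2 alone, with 1 library of day 4, Casp14, Sdha, Thrsp and Pvalb and the skeletal muscle and mitochondrial respiration lists were no longer called, and limma-voom called 6490 genes lower.

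At day 12 the P wounds held genes of growing hair follicles, pigment cells and collagen matrix above the level of unwounded skin. Krt73 (ENSMUSG00000063661, chromosome 15, 101701743 to 101710802, minus strand), a keratin of the inner root sheath, lay at 487 ± 255 CPM (n = 6) against 0 counts, a rise of at least 18500-fold. Krt25 rose 24000-fold from 6 counts to 1720 ± 1000 CPM (n = 6), and the follicle morphogen Shh rose 265-fold. All 18 hair follicle genes rose (fry, adjusted p = 1.19e-06; adjusted p = 0.44 with an estimated correlation). So did all 5 melanocyte genes (fry, adjusted p = 1.19e-06; adjusted p = 0.44 with an estimated correlation), with Pmel up 228-fold, Dct 51.7-fold and Tyr 597-fold, and the stem cell factor receptor gene Kit rose 7.09-fold. All 18 matrix collagen genes rose (fry, adjusted p = 4.81e-05; adjusted p = 0.441 with an estimated correlation). Col1a1 rose 38.2-fold to 13200 ± 11300 CPM (n = 6), Bgn 14-fold and Tnc 45.3-fold.

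Inflammatory genes were still above unwounded skin at day 12. S100a9 lay at 57.7 ± 79 CPM (n = 6), 343-fold up, and 13 of 14 neutrophil genes rose (fry, adjusted p = 0.000147; adjusted p = 0.441 with an estimated correlation), the exception being Il1r2, which fell 3.47-fold. Mmp13 rose 574-fold, Timp1 51.9-fold and Plaur 10.6-fold. On the senescence-associated secretory list 16 of 24 genes rose and 1 fell (fry, adjusted p = 0.000401; adjusted p = 0.441 with an estimated correlation). Krt16 rose 118-fold, and 13 of 14 wound keratinocyte genes rose (fry, adjusted p = 0.000147; adjusted p = 0.441 with an estimated correlation). Of 9 basal keratinocyte genes 7 fell, 8 adjusted over the list alone (fry, adjusted p = 3.4e-06; adjusted p = 0.44 with an estimated correlation), and the hemidesmosome gene Dst fell 4.76-fold. The cytotoxic gene Gzmb rose 21.6-fold, from 4 counts in unwounded skin.

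All 18 proliferation genes remained up at day 12 (fry, adjusted p = 3.15e-09; adjusted p = 0.44 with an estimated correlation), with Birc5 up 6.67-fold. All 14 adipocyte genes were down (fry, adjusted p = 4.81e-05; adjusted p = 0.441 with an estimated correlation), Lep by 28.8-fold and Pnpla2 by 4.15-fold. Of 16 skeletal muscle genes 13 fell, 14 adjusted over the list alone (fry, adjusted p = 0.002; adjusted p = 0.441 with an estimated correlation), with Myh4 down 13.5-fold. Outside that list the muscle gene Mstn fell 40.9-fold, while Mymk rose 164-fold. Of 16 mitochondrial respiration genes 14 fell, 15 adjusted over the list alone (fry, adjusted p = 0.000223; adjusted p = 0.441 with an estimated correlation), with Sdha down 2.67-fold. Of 14 glycolysis and hypoxia genes 8 fell and 2 rose, and 9 fell adjusted over the list alone (fry, adjusted p = 8.79e-05; adjusted p = 0.441 with an estimated correlation), with Bnip3 down 5.93-fold and Ldha 3.05-fold. The p53 target Ccng1 fell 5.88-fold, Cyp2e1 41.1-fold and Il22ra2 60.4-fold. The day 12 fit called 4890 genes higher and 4138 lower, 43.7% of those tested, of which 3229 and 2221 by more than 2-fold, and 17 lists, 11 up and 6 down. The share of higher calls was 54.2%, and with no composition factor it was 73%, with the median of all genes shifted by 0.268 log2 and 2617 genes lower. Krt73 and Krt25 were no longer called within set 1 alone and Cyp2e1 with 2 surrogate variables, and limma-voom called 6569 genes lower.

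**Figure D2:**
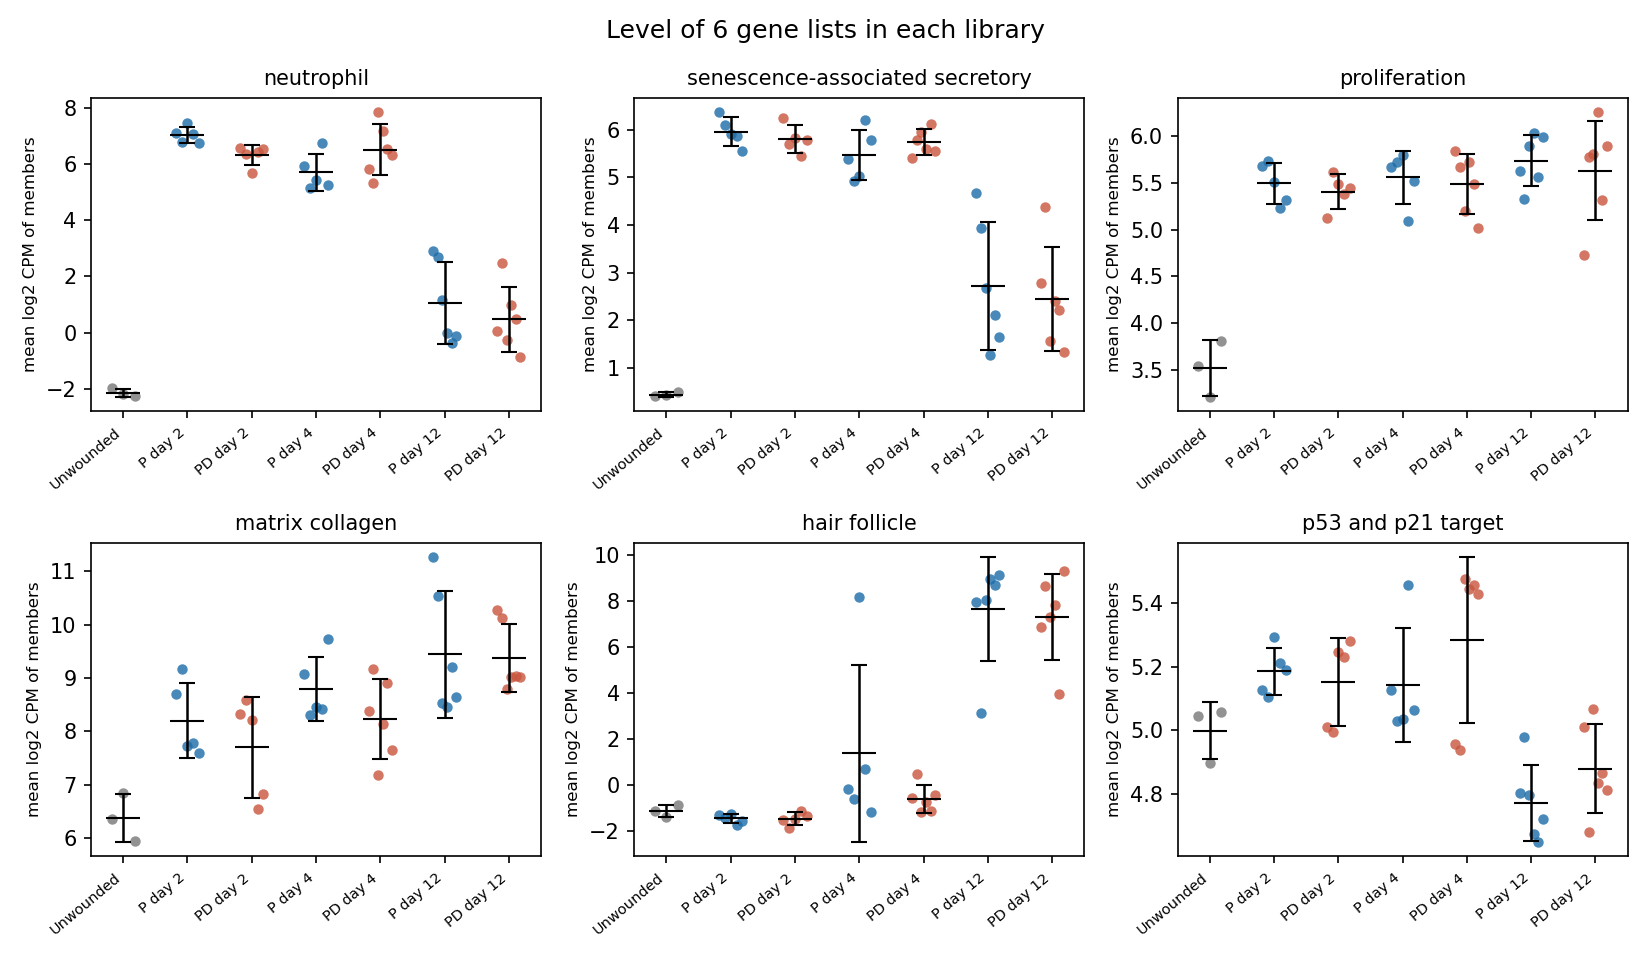
Level of 6 gene lists in each library. Each panel plots the mean log2 CPM of the list members per library on the vertical axis by group on the horizontal axis, with the group mean and SD. The neutrophil list falls by day 12, the hair follicle list is high at day 12 and in P day 4 replicate 3 at 8.17, and the proliferation list lies above unwounded skin in every wound group.

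The 33 wound libraries were parted into 2 sets by a fit to the data, and these sets cut across arm and day. On a scale with the set means at 0 and 1, the lowest library of set 1 scored 0.77 and the highest of set 2 scored 0.31, and the sets took up 28.9% of the variance within groups. The scores rest on the values that defined the sets, so this gap alone does not show that the libraries form separate sets. Set 1 held 15 libraries and set 2 held 18. Set 1 took in 2 of 5 libraries of P day 2, 3 of 5 of PD day 2, 4 of 5 of P day 4, 2 of 6 of PD day 4, 2 of 6 of P day 12 and 2 of 6 of PD day 12. The sets ran with the labelled replicate number: all 12 libraries numbered 1 or 2 were in set 1, and of 21 numbered 3 to 6, 18 were in set 2. The 3 exceptions were P day 4 replicates 3 and 5 and PD day 2 replicate 3. After removal of group means, set 1 libraries lay 1.97 log2 higher in the differentiated keratinocyte list, 1.80 in mast cell, 1.67 in wound keratinocyte, 1.67 in alternatively activated macrophage and 1.32 in matrix collagen genes. They lay 1.24 log2 lower in skeletal muscle genes (difference -1.24), and 0.02 apart in proliferation genes and -0.16 in p53 and p21 targets. The sets were defined from these same values, so no p-value between them is given, and the comparisons between wounds are given with and without a term for them.

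**Figure D3:**
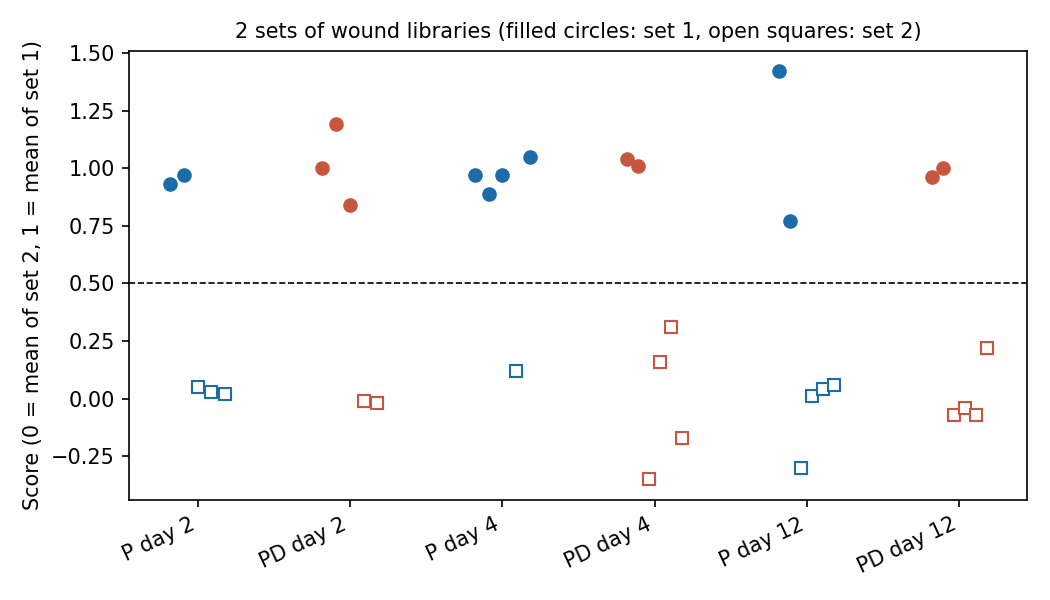
Score of each wound library on the axis that separates the 2 sets, from 0 at the mean of set 2 to 1 at the mean of set 1. Filled circles are the 15 libraries of set 1 and open squares the 18 of set 2, by group. No library lies between 0.31 and 0.77, a gap that the way the sets were defined favours.

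From day 2 to day 4 the P wounds gained genes of the cornifying epidermis and some genes of new muscle. Krt1 (ENSMUSG00000046834, chromosome 15, 101753861 to 101759229, minus strand), a keratin of the suprabasal layers, rose 14-fold from 397 ± 311 to 5570 ± 4040 CPM (n = 5 each). Flg, which makes filaggrin, rose 23.7-fold and Casp14 11.4-fold. Of 14 differentiated keratinocyte genes 11 rose, all 14 adjusted over the list alone (fry, adjusted p = 0.00297; adjusted p = 0.53 with an estimated correlation). This was the only list called of 31, and it was lost in a fit of only these 10 libraries (fry, adjusted p = 0.124). Myh3 rose 57.9-fold (log2 5.86, SE 0.72), the cardiac actin gene Actc1 31.7-fold and Mymk 7.91-fold, but only 3 of 8 muscle regeneration genes rose and the list was not called (fry, adjusted p = 0.157). The cell cycle inhibitor gene Cdkn2b rose 2.3-fold (SE of log2 0.21) and the lymphocyte gene Cd5 3.35-fold, whereas Cdkn1a was not called (log2 0.41, SE 0.20, edgeR, adjusted p = 0.207), though it was with a term for the library sets and with limma-voom. The macrophage gene Chil3 fell 9.7-fold, the acute phase gene Saa2 9.75-fold, the stretch-response gene Ankrd2 7.2-fold, Rrad 6.81-fold and Fgf2 2.07-fold. The contractile genes Acta2 and Myl9 rose 2.21-fold and 2.19-fold. Of 18 hair follicle genes 17 rose with the list not called (fry, adjusted p = 0.128).

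The fit called 1189 genes higher and 557 lower at day 4 than at day 2 in P wounds, 8.45% of those tested, of which 821 and 152 by more than 2-fold. Among the called genes named here the largest edgeR adjusted p was 0.019, for Acta2. The calls of Krt28 (273-fold), Krt33b (at least 1450-fold from 0 counts), Crnn (668-fold) and Pmel (11-fold) were lost without P day 4 replicate 3, with limma-voom and within either set alone. The calls of Acta2 and Myl9 were lost without P day 2 replicate 3 or replicate 5, that of Acta2 also without P day 4 replicate 5. Set 1 held 4 of 5 libraries at day 4 and 2 of 5 at day 2, and its libraries lay higher in the same differentiated keratinocyte genes. With a term for the sets 2047 genes were higher and 1057 lower, the differentiated keratinocyte list stayed called and the muscle regeneration list was called with it. Within set 2 alone, with 1 library at day 4, 189 and 30 genes were called, and Cdkn2b, Cd5, Chil3, Saa2, Ankrd2, Rrad and Fgf2 were not among them. Within set 1 alone 520 genes were higher, without Acta2 and Myl9, and limma-voom called 2888 and 3297 without a term for the sets. The counts moved most without P day 2 replicate 5 (693 higher, 244 lower), P day 2 replicate 4 (710 and 296), P day 4 replicate 1 (278 lower), P day 4 replicate 2 (325 lower) and P day 4 replicate 4 (1591 and 853). The number of lists called was 3 without P day 2 replicate 1 and 2 without P day 4 replicate 3.

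From day 4 to day 12 the P wounds lost inflammatory and hypoxia genes and gained pigment and hair genes. Retnlg fell 170-fold, Cxcl2 124-fold, Csf3 92.6-fold, Cd14 53.1-fold, Tnf 35.9-fold and Lcn2 25-fold (log2 -4.64, SE 0.48). Of 14 neutrophil genes 12 fell and 1 rose (fry, adjusted p = 1e-08; adjusted p = 0.0576 with an estimated correlation), and 6 of 14 monocyte and macrophage genes fell (fry, adjusted p = 0.00018; adjusted p = 0.228 with an estimated correlation). On the senescence-associated secretory list 12 of 24 genes fell and 0 rose, and 15 fell adjusted over the list alone (fry, adjusted p = 1.23e-05; adjusted p = 0.139 with an estimated correlation), with Il1a down 10.8-fold and Mmp9 8.62-fold. The senescence marker Plaur fell 16.1-fold (log2 -4.01, SE 0.46). Hdc fell 70.7-fold, Arg1 6.9-fold and Tgfb1 1.9-fold. Of 14 glycolysis and hypoxia genes 11 fell, 13 adjusted over the list alone (fry, adjusted p = 5.09e-09), and this list kept its call with an adjusted p = 0.0453 with an estimated correlation. In it Eno1 (ENSMUSG00000063524, chromosome 4, 150321073 to 150337027, plus strand) fell 2.66-fold from 919 ± 154 CPM (n = 5) to 346 ± 43.8 CPM (n = 6), the glucose transporter gene Slc2a1 4.2-fold and Vegfa 2.17-fold.

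The immediate early genes fell over the same days, 9 of 10 and all 10 adjusted over the list alone (fry, adjusted p = 7.02e-06; adjusted p = 0.139 with an estimated correlation), with Junb down 5.33-fold and Fos 6.39-fold. Of 14 wound keratinocyte genes 9 fell, 12 adjusted over the list alone (fry, adjusted p = 0.00018; adjusted p = 0.228 with an estimated correlation). Krt6a fell 6.06-fold, though reads shared with Krt6b leave the share of each uncertain, and Krt14 fell 3.48-fold. Of 20 p53 and p21 targets 6 fell, and 7 fell and 1 rose adjusted over the list alone (fry, adjusted p = 0.000191; adjusted p = 0.228 with an estimated correlation), with Fas down 3.31-fold beside Cdkn1a. All 5 melanocyte genes rose (fry, adjusted p = 3.83e-06; adjusted p = 0.139 with an estimated correlation), including Pmel (ENSMUSG00000025359, chromosome 10, 128540064 to 128556107, plus strand) by 36.4-fold, Tyrp1 by 35.7-fold and Dct by 21.5-fold, and the melanocortin receptor gene Mc1r, not on that list, rose 27.6-fold. Of 18 hair follicle genes 5 rose (fry, adjusted p = 1.44e-05; adjusted p = 0.139 with an estimated correlation), with Shh up 7.5-fold. P day 4 replicate 3 lay at 8.17 mean log2 CPM in this list and the other P day 4 libraries at 0.7 or less. That replicate raised the day 4 mean of the list and so lowered its rise to day 12. The matrix gene Postn rose 3.46-fold, and Sox10 rose 3.54-fold.

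The fit called 2318 genes higher and 2604 lower at day 12 than at day 4 in P wounds, 23.8% of those tested, of which 920 and 1401 by more than 2-fold, and 16 lists, 3 up and 13 down. Among the genes named here the largest edgeR adjusted p was 0.00345, for Krt6a. Set 1 held 4 of 5 libraries at day 4 and 2 of 6 at day 12, and keratinocyte, macrophage and collagen genes lay higher in it. With a term for the sets 3065 genes were higher and 2995 lower. Within set 1 alone 1230 were higher and 930 lower, with 9 lists called, and Pmel, Tyrp1, Shh, Sox10, Cxcl2, Mmp9, Vegfa, Fas, Tgfb1 and Arg1 were no longer called, nor were the monocyte and macrophage, senescence-associated secretory, p53 and p21 target and hair follicle lists. Within set 2 alone, with 1 library at day 4, Krt14 was no longer called. limma-voom called 5289 and 5414 genes. The share of higher calls was 47.1%, and with no composition factor it was 69.6%, with 3977 genes higher and the median of all genes shifted by 0.181 log2. Without P day 12 replicate 6 the lists called numbered 10.

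At day 2 the PD and P wounds did not differ in any gene past the threshold. Arg1, a macrophage and wound gene, lay at 162 ± 48.3 CPM in PD and 450 ± 103 CPM in P wounds (n = 5 each), a log2 difference of -1.47 (SE 0.69, edgeR, adjusted p = 1). Inhba differed by -1.02 (SE 0.47) and Plaur by -0.53 (SE 0.44), each with an edgeR adjusted p of 1. The interferon-induced genes Cxcl10 and Ifit3 differed by 1.45 (SE 0.56) and 1.33 (SE 0.58), the fat hormone gene Lep by 1.76 (SE 0.74) and Gdf15 by 0.94 (SE 0.49). None of these passed. Eno1 differed by -0.40 (SE 0.12). Of 14 glycolysis and hypoxia genes 0 passed among all genes and 1 was lower adjusted over the list alone (fry, adjusted p = 0.982), and this list was called in a fit of only the 10 libraries of day 2. Of 20 p53 and p21 targets, 10 senescence markers and 24 senescence-associated secretory genes 0 passed (fry, adjusted p = 0.982 for each list).

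The day 2 comparison of the arms called 0 genes higher and 0 lower with edgeR, with 793 genes at unadjusted p under 0.05. Without any difference or library sets 1033 would pass on average. DESeq2 called 7 higher and 17 lower, limma-voom with sample weights 0 and 1, and limma-voom with a term for the sets 10 and 26. In simulated counts with these group sizes, edgeR recovered 19.4% of 1.5-fold, 61.2% of 2-fold and 90.9% of 4-fold changes.

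At day 4 many of the genes nearest to the threshold between PD and P wounds were those of the hair follicle. Tchh (ENSMUSG00000052415, chromosome 3, 93349637 to 93356384, plus strand), which makes trichohyalin, lay at 564 ± 1250 CPM in P (n = 5) and 4.16 ± 2.88 CPM in PD wounds (n = 6). Its log2 difference was -7.07 (SE 1.40, edgeR, adjusted p = 0.0808), beside Padi3 at -5.63 (SE 1.12), Krt35 at -6.90 (SE 1.42) and Krt28 at -5.58 (SE 1.17) with the same adjusted p. The P mean came from P day 4 replicate 3. Of 18 hair follicle genes 0 passed among all genes and 17 were lower adjusted over the list alone (fry, adjusted p = 0.507). Without P day 4 replicate 1, 2, 4 or 5 each of these 4 genes was called, and 27, 27, 29 and 26 genes were lower in PD wounds. Without PD day 4 replicate 2 there was 1 gene lower, and without P day 4 replicate 4 there were 2 higher.

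Other genes at day 4 were not called either. The death receptor gene Fas differed by 0.80 (SE 0.30, edgeR, adjusted p = 0.38), Lcn2 by 0.97 (SE 0.43, adjusted p = 0.405), Cdkn2b by -0.51 (SE 0.20, adjusted p = 0.391) and the wound keratin gene Krt17 by -1.11 (SE 0.45, adjusted p = 0.393). Of 14 differentiated keratinocyte genes 0 passed (fry, down, adjusted p = 0.507), while set 1, whose libraries lay higher in these genes, held 4 of 5 P and 2 of 6 PD libraries. The immediate early list also missed the threshold (fry, up, adjusted p = 0.507). Of 20 p53 and p21 targets 0 passed (fry, adjusted p = 0.507), as of 24 senescence-associated secretory genes (fry, adjusted p = 0.655). The 10 senescence markers had a median log2 difference of -0.01 and a mean of 0.06, with the test pointing up (fry, adjusted p = 0.943).

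The day 4 comparison of the arms called 0 genes with edgeR, with 2369 genes at unadjusted p under 0.05. Without any difference or library sets 1033 would pass on average. In fits of only these libraries, 30 of 100 groupings, the labelled one included, had as many such genes as the labelled one. DESeq2 called 12 higher and 172 lower, and limma-voom with sample weights called 975 and 1081, among them Cdkn1a, Fas, Lcn2, Cdkn2b and Krt17. These fits had no term for the sets, while set 1 held 4 P and 2 PD libraries and set 2 held 1 and 4. Without P day 4 replicate 4, the only P library of set 2, edgeR put 4536 genes at unadjusted p under 0.05. What part of the limma-voom calls ran with the sets is therefore open. With a term for the sets edgeR called 0, and within set 2 alone, with 1 P library, 9 genes were lower. In simulated counts edgeR recovered 14.9% of 1.5-fold, 59.7% of 2-fold and 84.8% of 4-fold changes.

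At day 12 no gene differed between the arms past the threshold. The cytokine gene Il6 lay at 0.407 ± 0.257 CPM in PD and 2.19 ± 3.15 CPM in P wounds (n = 6 each; log2 -2.41, SE 0.66, edgeR, adjusted p = 0.884). The contractile genes Actg2 and Cnn1 differed by -1.14 (SE 0.33) and -1.18 (SE 0.35), Ccn2 by -0.62 (SE 0.21), and the cornified envelope genes Sprr2f and Sprr2d by -3.93 (SE 1.23) and -3.34 (SE 1.08). Mmp12 differed by 1.54 (SE 0.57), Tnf by 1.53 (SE 0.64), and the p53 targets Ccng1 and Eda2r by 0.89 (SE 0.36) and 0.78 (SE 0.32). All of these had an edgeR adjusted p of 0.884. Of 8 contractile genes 0 passed among all genes and 2 were lower adjusted over the list alone (fry, down, adjusted p = 0.384). Of 14 wound keratinocyte genes 0 passed and 2 were lower adjusted over the list alone (fry, down, adjusted p = 0.384). The skeletal muscle list had 0 of 16 genes past the threshold (fry, up, adjusted p = 0.384). Of 20 p53 and p21 targets, 10 senescence markers and 24 senescence-associated secretory genes 0 passed among all genes, and 1 secretory gene, Il6, was lower adjusted over the list alone (fry, adjusted p = 0.818 for each list).

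The day 12 comparison of the arms called 0 genes with edgeR, and 0 with DESeq2 and with limma-voom. With edgeR 1022 genes were at unadjusted p under 0.05, where 1033 would pass on average without any difference or library sets. DESeq2 with a term for the sets called 1 higher and 2 lower, and within set 2 alone 2 lists were called. In simulated counts edgeR recovered 25.4% of 1.5-fold, 49.3% of 2-fold and 92.4% of 4-fold changes.

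Averaged over the 3 days, Cdkn1a was not called between PD and P wounds (log2 0.19, SE 0.11, edgeR, adjusted p = 0.444). The difference was 0.13 with a term for the sets, -0.03 within set 1, 0.21 within set 2 and 0.01 with 2 surrogate variables. The average difference called 0 genes with edgeR, with 2488 at unadjusted p under 0.05. Without any difference or library sets 1033 would pass on average. In fits of the wound libraries alone, 10 of 100 groupings, the labelled one included, reached the labelled number of 2310. DESeq2 called 16 higher and 88 lower, and limma-voom with sample weights 1 and 0. The wound keratinocyte list had 0 of 14 genes past the threshold and 2 lower adjusted over the list alone (fry, down, adjusted p = 0.57). Simulated changes of 1.5-fold were recovered at 62.7% and of 2-fold at 89.6%. Whether the arm difference changed between days was tested directly. For Cdkn1a the change in the arm difference was 0.64 log2 from day 2 to day 4 (SE 0.27, edgeR, adjusted p = 0.683), called with limma-voom only, and 0.64 from day 2 to day 12 (adjusted p = 1).

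The day 4 against day 2 change in the arm difference called 0 genes with edgeR (1472 at unadjusted p under 0.05), DESeq2 called 7 and 71, and limma-voom with sample weights 1417 and 1380. With no composition factor its median over all genes shifted by -0.117 log2. The day 12 against day 4 change called 0 with edgeR (623 at unadjusted p under 0.05), 86 and 3 with DESeq2, and 0 and 1 with limma-voom. The day 12 against day 2 change called 0 with edgeR (547 at unadjusted p under 0.05) and with limma-voom, and 13 and 8 with DESeq2. Of 8 contractile genes 0 passed for that change and 4 were lower adjusted over the list alone (fry, down, adjusted p = 0.278). With fry on all 36 libraries none of the 31 lists was called in any comparison of the arms. The exceptions in other fits were the glycolysis and hypoxia list at day 2 with only those libraries (fry, down, adjusted p = 0.0374), and the muscle regeneration list (up) and the Schwann cell list (down) at day 12 within set 2 alone (fry, adjusted p = 0.0331 each). Camera with the preset correlation called 7, 11 and 11 lists at days 2, 4 and 12, and 0 with an estimated correlation.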

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

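The 8 tests of explanations in this part, on the library sets, the hair genes and Cdkn1a, were chosen only after those results were seen. In 204 combinations of a group with a list level, Cdkn1a, depth or mitochondrial share, a library was singled out where its distance to the nearest library was a large share of the group's range. This happened in 12 of them (5.9%), where 10.2 would by chance, a number close to this.

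In P day 4 wounds, replicate 3 stood apart in the hair follicle list, at 8.17 mean log2 CPM against 0.7 for the next library (distance 0.8 of the range). Replicate 4 of the same group stood apart in 4 measures. It was low in the mast cell list at 0.75 against 2.35 (distance 0.77) and in the Schwann cell list at 1.87 against 3.07 (distance 0.866). It was high in the p53 and p21 target list at 5.46 against 5.13 (distance 0.77) and in mitochondrial share at 4.98% against 2.86% (distance 0.843). Replicate 4 was the only set 2 library of P day 4, and all 4 measures ran in the direction of set 2. Set 1 minus set 2 was 1.8 log2 for the mast cell list, 0.47 for the Schwann cell list and -0.16 for the p53 and p21 target list. Mean mitochondrial share was 2.81% in set 1 and 4.14% in set 2. In P day 12 wounds, replicate 2 was low in the hair follicle list at 3.16 against 7.95 (distance 0.802), and replicate 1 was low in the sebaceous gland list at 3.5 against 4.53 (distance 0.674) and in the muscle regeneration list at 2.25 against 4.27 (distance 0.675). In PD day 12 wounds, replicate 2 was low in the muscle regeneration list at 3.7 against 5.12 (distance 0.706). In PD day 2 wounds, replicate 3 was low in the neutrophil list at 5.7 against 6.37 (distance 0.762) and high in the erythroid list at 7.18 against 4.6 (distance 0.866). Replicate 4 of that group was high in mitochondrial share at 5.68% against 3.95% (distance 0.736).

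The 2 sets of wound libraries differed in 519 genes without overlap after removal of group means, and in mitochondrial share, at a mean of 2.81% in set 1 and 4.14% in set 2, and they ran with the labelled replicate number, with all 12 libraries numbered 1 or 2 in set 1 and 18 of 21 numbered 3 to 6 in set 2. Totals overlapped between set 1 (24.951 to 47.378 M) and set 2 (11.807 to 41.315 M), with 12 set 2 libraries deeper than the shallowest of set 1, so depth alone did not part the sets, while a share for depth stays open, since the highest score of those 12, at 0.31, was bound to be low by how the sets were defined. More muscle in set 2 would lower all other cell types alike. The differences of 14 lists of other cell types ran from -0.67 (SE 0.2, sebaceous gland) to 1.97 (SE 0.29, differentiated keratinocyte), 2.64 log2 apart (SE 0.35). That last SE takes the 2 lists as independent and covers neither their choice as extremes nor that the sets came from these values. The gap therefore speaks only against muscle as the sole difference. A lower yield of membrane and secreted mRNAs in set 2 alike in all cell types was argued against by muscle markers. That class differed there by 0.08 log2 from the cytosolic class (bootstrap SD 0.13). In keratinocyte markers the difference was -0.23 (SD 0.14), the other way. But the keratinocyte lists themselves parted between the sets, at 1.97 log2 for differentiated and 0.11 for basal genes. Whether that shift entered the keratinocyte value was not tested. Myeloid markers went with a lower yield at 0.39 (SD 0.12), or 0.28 (SD 0.1) after removing the trend with length and GC. Removing the trend with transcript length and GC content left a median difference of 0.55 of 0.66 log2 in those 519 genes (bootstrap SD 0.02). These genes were picked for their difference between the sets, so they were bound to keep much of it, and the SD does not cover that choice. Over 20549 genes length and GC explained 8.5% of the variance of the set difference, and what part of the sets they account for stays open. A batch of surgery, handling or sequencing that ran with the replicate number stays open, as do the site and depth of the biopsy, since the labels record none of these, and no biological explanation was tested.

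Hair follicle genes in P day 4 replicate 3 lay at 8.17 mean log2 CPM, within the range of P day 12 wounds (3.16 to 9.13). A day 12 library under a day 4 label was argued against by its neutrophil list level of 5.44, above the highest P day 12 library at 2.89 by more than their SD of 1.46. Growing follicles in the biopsy would bring pigment cells, and the melanocyte list lay at 3.79, above the other P day 4 libraries (at most 1.21, SD 0.71). It lay below every P day 12 library (3.93 to 7.69), unlike the hair follicle list. Raised pigment genes go with follicles in growth in that sample, but short of the day 12 level, and RNA carried over from another library is not excluded. Whether the animal's hair cycle or the biopsy site differed was not tested.

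In the fit of all libraries Cdkn1a was not lower in PD than in P wounds at days 4 and 12. At day 12 each arm held 2 libraries of set 1 and 4 of set 2, so the sets were not uneven there. With this balance the 0.39 log2 (SE 0.13) left by a term for the sets tests uneven sets no further. In that fit, chosen after the data were seen, the edgeR p was 0.0051 before adjustment over genes and 0.456 after it. The difference was 0.48 and 0.38 within sets 1 and 2 alone, and 0.22 with 2 surrogate variables (edgeR, unadjusted p = 0.0707). At day 4 it was 0.41 without that term and 0.18 (SE 0.14) with it. It was -0.06 within set 1, 0.13 with 2 surrogate variables and 0.11 within set 2, whose P arm is 1 library. Cdkn1a parted by set at that day without overlap, at 381.9 to 512.6 CPM in set 1 and 716.3 to 823.4 CPM in set 2, with libraries of both arms in each. Set 1 held 4 of 5 P and 2 of 6 PD libraries at day 4, so the higher PD mean there went with the uneven sets. Within set 1 alone the day 2 difference was -0.52 log2 (SE 0.16, edgeR, adjusted p = 0.713), and within set 2 alone 0.13. It was -0.17 with a term for the sets and -0.33 with 2 surrogate variables at that day. Too few reads were argued against by a lowest count of 5288 among the wound libraries, while a small share of cells with high Cdkn1a, lost within a whole biopsy, and the timing of their removal stay open and were not tested.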

How the results depend on the processing

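The tests with surrogate variables and with the library sets were chosen only after the results were seen. Of 199 gene results picked for the text, 4749 alternative values were computed. Of these, 4593 stayed on their side of the threshold, 119 lost their call, 37 gained it and 0 changed sign while called in the report's fit or in the alternative. The 4593 include 32 that changed sign without a call in either fit. Of 372 list results (31 lists in 12 comparisons) with 8773 alternative values, 8419 stayed, 187 lost their call, 161 gained it and 6 changed direction while called in 1 of these fits. The 8419 include 635 that changed direction without a call in either fit. Leaving out a library changed no other call of a gene or list named in the report than those given there, and moved no other count by over 1.5 times than those given here. The comparisons of the arms depend on the tool. The limma-voom calls with sample weights that involve the arms at day 4 had no term for the sets, which were uneven there. Depth limits genes near the filter. In simulated counts 1.5-fold changes were recovered at 14.9% to 25.4% for the arms on single days and at 62.7% in the mean of days. Most differences of that size between the arms on a single day would therefore be missed. The changes between days were not simulated. The planned sex term was not run. Except where fewer libraries were fitted, the cause of the changes below was not tested.

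With the DESeq2 Wald test the arms differed in 7 genes higher and 17 lower at day 2, 12 and 172 at day 4, and 16 and 88 in the mean of days. The changes in the arm difference were called in 7 and 71 genes (day 4 against day 2), 86 and 3 (day 12 against day 4) and 13 and 8 (day 12 against day 2). With limma-voom and sample weights the arms differed in 1 gene lower at day 2, 975 higher and 1081 lower at day 4 and 1 higher in the mean, and the changes in 1417 and 1380 (day 4 against day 2) and 1 lower (day 12 against day 4). It called 6223, 6490 and 6569 genes lower in P wounds of days 2, 4 and 12 than in unwounded skin, 2888 and 3297 between P days 4 and 2, and 5289 and 5414 between P days 12 and 4.

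With the set term edgeR called 2047 and 1057 genes between P days 4 and 2, limma-voom 2712 and 2418, and DESeq2 2566 and 1465. Between P days 12 and 4 limma-voom with the set term called 5315 and 4976. For the arms, limma-voom with the set term called 10 and 26 at day 2. DESeq2 with the set term called 9 and 23 at day 2, 7 and 138 at day 4, 1 and 2 at day 12, and 89 and 130 in the mean. For the changes it called 16 and 95 (day 4 against day 2), 73 and 13 (day 12 against day 4) and 12 and 8 (day 12 against day 2). Within set 1, with fewer libraries, 520 genes were higher at P day 4 than day 2, and 1230 higher and 930 lower at P day 12 than day 4. Set 2 held 1 P library of day 4, on which all its results with P day 4 rest. Within set 2 the arms differed in 1 gene lower at day 2, 9 lower at day 4 and 2 lower in the mean. The changes within set 2 were 1 lower (day 4 against day 2) and 2 higher (day 12 against day 2), and P days 4 and 2 differed in 189 and 30.

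With only the libraries of the comparison 774 genes were higher and 364 lower at P day 4 than day 2, and 1458 higher at P day 12 than day 4. With no composition factor 2617 genes were lower at P day 12 than in unwounded skin and 3977 higher at P day 12 than day 4. With no filter 292 genes and with 2 surrogate variables 1375 genes were lower at P day 4 than day 2.

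For the lists, camera with an estimated correlation called 0 in the comparisons with unwounded skin and between P days 4 and 2, and 1 between P days 12 and 4. Camera with the preset correlation called 7, 11 and 11 for the arms at days 2, 4 and 12, 10 for the mean, 13, 12 and 14 for the changes (day 4 against day 2, day 12 against day 4, day 12 against day 2), and 10 between P days 4 and 2. It takes the genes of a list as nearly independent. With only the libraries of the comparison 1 list was called for the arms at day 2 and 0 between P days 4 and 2. Between P days 4 and 2, 5 lists were called with 2 surrogate variables, 2 with the set term, 6 within set 1 and 5 within set 2. Within set 2, 2 lists were called for the arms at day 12, and within set 1, 9 between P days 12 and 4.

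The lists that changed direction while called in 1 of the fits did so as follows, the first 3 of them not called in the report's fit. The B and plasma cell list was called at P day 2 against unwounded skin with only those libraries (fry, adjusted p = 0.0445). The alternatively activated macrophage list was called at P day 12 against unwounded skin with 2 surrogate variables (adjusted p = 0.00256) and within set 1 (adjusted p = 0.00265). The mast cell list was called between P days 4 and 2 within set 1 (adjusted p = 0.0318). Between P days 12 and 4 within set 1 the matrix protease list (adjusted p = 0.134) and the wound growth factor list (adjusted p = 0.49) turned without being called there.

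Leaving out 1 library at a time gave these ranges. For the arms at day 4 the genes higher ran from 0 to 2 and lower from 0 to 29. The genes lower at P day 4 than in unwounded skin ran from 2710 to 4052. Between P days 4 and 2 the genes higher ran from 693 to 1591, lower from 244 to 853, and lists from 1 to 3. Between P days 12 and 4 the lists ran from 10 to 15.

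The labels give replicate numbers but no shared animal, litter or day, so the libraries were not taken as paired. Most same-number pairs of the arms correlated over 0.1, and the correlations do not settle whether such libraries were linked. Correlations of same-number libraries after removal of group means ran from -0.253 to 0.463 for the arms at day 2, -0.138 to 0.209 at day 4 and -0.105 to 0.535 at day 12, with 4 of 5, 4 of 5 and 4 of 6 pairs over 0.1. Of the libraries compared, 2 of 5, 0 of 5 and 2 of 6 correlated best with their own number. Replicates 1 and 2 were in set 1 in every wound group and most others in set 2, so these correlations do not part the sets from any other link between same-number libraries. With the replicate number as a block the arms differed in 0 genes in every comparison. Against unwounded skin it called 4913 and 4374, 5092 and 4375, and 4961 and 4373 genes at days 2, 4 and 12, 1383 and 720 between P days 4 and 2 and 2495 and 2980 between P days 12 and 4. The lists called were 22, 21, 18, 2 and 15 in the same order.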

Other observations

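In this part the correlation with a term for the library sets and the fits within a set were chosen only after the results were seen. The cell cycle inhibitor genes Cdkn2a and Cdkn1a, both linked with senescence, moved in opposite directions late in the P wounds, and Cdkn2b was not called (log2 0.34, SE 0.20, edgeR, adjusted p = 0.233). Cdkn2a (ENSMUSG00000044303, chromosome 4, 89192708 to 89212890, minus strand) rose 3.96-fold from 0.398 ± 0.138 CPM at day 4 (n = 5) to 1.59 ± 0.532 CPM at day 12 (n = 6; log2 1.98, SE 0.50, edgeR, adjusted p = 0.00415), while Cdkn1a fell. Its call was lost within either library set alone, where fewer libraries were fitted and set 2 held 1 P library of day 4. Over the same days the T-cell genes Lck and Trac rose 2.49-fold (edgeR, adjusted p = 0.000139) and 3.43-fold (adjusted p = 0.00436). Of 13 T and NK cell genes 3 rose, 5 adjusted over the list alone (fry, adjusted p = 0.0361; adjusted p = 0.594 with an estimated correlation). This list lost its call within either set alone and without P day 12 replicates 2, 5 or 6 or P day 4 replicates 1, 3 or 4.

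Interferon response genes had a median difference of 0.89 log2 between the arms at day 2 over 20 genes, with 0 past the threshold (fry, up, adjusted p = 0.982), and 14 adipocyte genes had a median of 1.03 log2, also with 0 past it (fry, up, adjusted p = 0.982). Across 20657 genes, which are not independent replicates, the PD minus P log2 differences of days 4 and 12 correlated at r = 0.294 (0.21 to 0.382 with each library left out), and at 0.186 with a term for the library sets. By rank they correlated at 0.463, and over the 12497 genes above 5 CPM at 0.355, by rank 0.62. The differences of days 2 and 4 correlated at -0.01 (-0.105 to 0.042), by rank -0.059, and above 5 CPM at 0.024 and -0.085. Those of days 2 and 12 correlated at 0.079 (-0.049 to 0.154), by rank 0.11, and above 5 CPM at 0.073 and 0.133.

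The labelled groupings were set against others of the same libraries, each refitted with edgeR on those libraries alone. For P wounds against unwounded skin only the labelled grouping, 1 of 56 at day 2, 1 of 56 at day 4 and 1 of 84 at day 12, called as many genes (8885, 8043 and 8283, with 324, 1 and 0 as the highest of the others), so an arbitrary grouping is excluded as the source. Between P days 4 and 2, 2 of 100 groupings called as many as the labelled 1138, the highest other 1862. Between P days 12 and 4, 3 of 100 called as many as 3312, the highest other 4077. A share under 0.05 makes an arbitrary grouping unlikely as the source there but does not exclude it. The highest other grouping in each followed the library sets, with 5 set 1 libraries of 5 against 1 and 5 of 6 against 1.

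For the arms 0 genes were called by edgeR, so that 100 of 100 groupings called as many at day 2, day 4 and day 12, in the mean of days and in each change of the difference between days, which with 0 calls could not have come out otherwise and says nothing for or against the arms. By genes at unadjusted p under 0.05, 25, 30 and 45 of 100 groupings reached the labelled number at days 2, 4 and 12 (1146, 1033 and 532). The numbers were 10 of 100 for the mean, and 13, 86 and 64 of 100 for the changes between days, so an arbitrary grouping is not excluded for any of them. The highest of the other groupings called 5499 genes at day 2, 3819 at day 4, 0 at day 12, 103 in the mean, and 967, 3508 and 335 in the changes (day 4 against day 2, day 12 against day 4, day 12 against day 2). Those at days 2 and 4 parted the sets, with 5 set 1 libraries of 5 against 0 at day 2 and 5 of 5 against 1 of 6 at day 4, which points to a structure of the samples other than the arms. With a term for the sets edgeR still called 0 genes for the arms.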
